A study of Homo sapiens with 12 samples.

How the data were processed

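Bulk RNA sequencing was carried out on 12 libraries of the human breast cancer cell line MDA-MB-468. Per the labels, the cells had been kept for 10 days in 0.5 µM EPZ5676 or in its solvent DMSO and were then separated by fluorescence-activated sorting into ALDH1+ and ALDH1- populations. The 2 treatments and 2 populations give 4 groups with 3 libraries each. The labels call the replicates biological. Per the labels' protocols, libraries were made from total RNA with a directional kit, which marks the strand of each transcript. The submitters' processing notes name Trim Galore, STAR and the genome build hg19, without versions. The counting program, its strand setting and the gene annotation are not given in the sources used here.

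The authors deposited 1 table of whole-number read counts per gene, with no normalization, and all values below were computed from it. The table holds 57783 genes under versioned Ensembl identifiers and 1 column per library. Column names were matched to the labels by treatment, population and replicate number. The columns call the DMSO cells untreated and the EPZ5676 cells treated. Identifiers were matched, without their version, to symbols in a table built from a GENCODE annotation: 51959 had a symbol, 5824 had none, and 932 matched genes share a symbol with another gene. No annotation of build hg19 was used here, so genes are given by symbol and without coordinates. Genes that share sequence with a close copy, and genes that overlap another on either strand, carry uncertain counts, since how the counting treated such reads is not given. The table has 0 mitochondrially encoded genes, so no mitochondrial share could be computed. Genes with a symbol took 99.13 to 99.18% of the counts of each library.

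Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr by group, which left 16327 genes, 91.1% of them with a symbol. Library sizes were scaled by the trimmed mean of M values (TMM), whose factors lay between 0.975 and 1.021. All 12 libraries were fitted in 1 quasi-likelihood model with a term per group. Each of 6 comparisons was tested with the quasi-likelihood F test. These were EPZ5676 against DMSO in each population, ALDH1+ against ALDH1- in each treatment, the difference between both treatment effects (interaction), and the treatment effect averaged over both populations. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called below an adjusted p of 0.05. Standard errors (SE) of log2 fold changes were obtained from the fold change and its F statistic. Levels are given in CPM, counts per 1000000 counts of the TMM-scaled library, as the mean ± SD of 3 libraries. The common biological coefficient of variation was 9.6%.

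Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2. P-values were adjusted over the lists of each comparison. The test asks whether the genes of a list are higher or lower than the other genes. Each list was tested again with an estimated correlation between its genes, and with fry, which asks whether the genes of a list move, on balance, in 1 direction. Of 32 lists, 31 had at least 3 measured genes; 24 of 739 list entries had no gene of that symbol in the table.

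The samples, groups, main tests, lists, alternative settings and the rule for naming genes were fixed before the data were examined. The rule named DOT1L, ALDH1A1, ALDH1A2, ALDH1A3, ALDH3A1 and MYC in every comparison. It added the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 1 whose replicates did not overlap between groups, or 5 and 5 for the interaction. It also allowed up to 4 members with the smallest p from each list with at least 1 called gene. Some genes that the rule allowed are not reported here. Genes named outside the rule are said to be so where they appear. The comparison of ALDH1+ with ALDH1- averaged over both treatments was added after the data were seen.

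The replicate numbers recur in all 4 groups, and whether they pair the libraries was checked before calls were compared. Over 12354 genes, deviations from the group means of libraries with the same number in different groups had correlations from 0.17 to 0.65 in all 18 such pairs. Between libraries with different numbers the correlations ranged from -0.66 to 0.22. In all 18 cases a library correlated best with its own number, so the numbers pair the libraries. A fit with the replicate number as a block had been set down beforehand as an alternative, and its values stand beside the results where they differ in call or by over 1.5 times.

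Other alternatives were median-ratio (RLE) scaling, total counts without scaling factors, no filter, a filter of at least 1 CPM in 3 samples, the DESeq2 1.42.0 Wald test, limma-voom, a fit of only the groups compared, and leaving out each library in turn. After the data were seen, 3 more were added. They were libraries thinned at random to 24348594 counts (the total of the shallowest), both EPZ5676 libraries numbered 3 left out, and the block together with thinning. Other splits of the libraries into groups of the same size were also tested.

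The procedure was tested on simulated counts with the means and library sizes of these samples. For EPZ5676 against DMSO in ALDH1+ it ran on 16047 genes and recovered 57.6% of genes changed 1.5-fold, 89.4% of those changed 2-fold and 100% of those changed 4-fold, with 8.9% false genes among its calls. For ALDH1+ against ALDH1- in DMSO it ran on 16053 genes and recovered 70.3, 81.5 and 96.9% at the same folds, with 8.5% false genes among its calls. The simulation had no shared variation between libraries of the same number. Counts of a few reads are imprecise: 3 counts, the limit that a count of 0 allows at a confidence of 95%, correspond to 0.0374 to 0.123 CPM depending on the library. This limit covers counting error only, since reads without molecular identifiers are not independent molecules.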

Results

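Gene expression was measured by bulk RNA sequencing in MDA-MB-468, a cell line of triple-negative breast cancer, which lacks the estrogen and progesterone receptors and amplified HER2. Cells had been treated for 10 days with 0.5 µM EPZ5676 (pinometostat), a small-molecule inhibitor of the histone H3 lysine 79 methyltransferase DOT1L, or with the solvent DMSO. They were then sorted by flow cytometry for ALDH1, an aldehyde dehydrogenase activity used to enrich breast cancer cells with stem cell traits. The 4 groups, DMSO ALDH1+, DMSO ALDH1-, EPZ5676 ALDH1+ and EPZ5676 ALDH1-, had 3 replicates each. Replicates 1, 2 and 3 had total counts of 27728085, 25441302 and 58004508 in DMSO ALDH1+ and 27353732, 29310374 and 26074535 in DMSO ALDH1-. They had 28230029, 80195050 and 29368821 in EPZ5676 ALDH1+ and 24348594, 27937027 and 24856576 in EPZ5676 ALDH1-. No pair of replicates was alike within counting error, with a chi-square per degree of freedom between 3.92 and 34.12.

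Treatment was the main axis of variation. The first principal component held 62.3% of the variance and parted all 6 EPZ5676 libraries from all 6 DMSO libraries, and the second held 10.3%. The EPZ5676 libraries numbered 3 lay closer to DMSO than the other EPZ5676 libraries, at 26.8 in ALDH1+ and 27.3 in ALDH1- on the first component against 40.5 to 42.5. The DMSO libraries numbered 3 were shifted the same way. They lay at -47.4 in ALDH1+ against -37.6 and -37, and at -39.1 in ALDH1- against -26.3 and -32.4. These positions alone therefore do not show a weaker response in replicate 3.

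**Figure D1:**
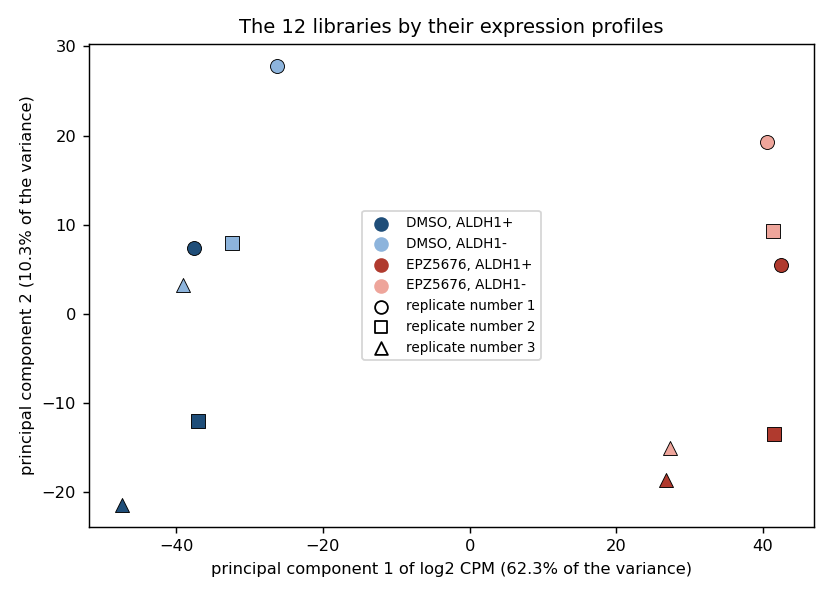
Principal components of log2 CPM over the genes tested, with 1 point per library (first component, 62.3% of variance, on the horizontal axis; second, 10.3%, on the vertical axis). The 6 EPZ5676 libraries lie at positive and the 6 DMSO libraries at negative values of the first component.

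The response to DOT1L inhibition was examined first in ALDH1+ cells. PRR9, SPRR3, GAD1 and GREM1 were among the 8 largest rises. PRR9 (ENSG00000203783.4), a proline-rich gene of the epidermal differentiation complex, went from 0.886 ± 0.51 CPM in DMSO to 48.6 ± 14 CPM in EPZ5676 (SD, n = 3), a log2 fold change of 5.89 (SE 0.30, adjusted p = 1.0e-08). The cornified envelope gene SPRR3 went from 0.374 ± 0.14 to 13 ± 2.9 CPM (log2 fold change 5.09, SE 0.27). GAD1, the enzyme that makes GABA, rose by 4.64 (SE 0.21) and the BMP antagonist GREM1 by 4.39 (SE 0.28). The 8 largest falls included ATP13A5, a P5-type ATPase, which fell by 4.42 on the log2 scale (SE 0.27), and the homeobox gene EN1, which fell by 2.96 (SE 0.18), from 10.2 ± 1.3 to 1.34 ± 0.12 CPM. SYT12 fell by 2.82 (SE 0.17), the death ligand TNFSF10 (TRAIL) by 2.62 (SE 0.20) and the hypoxia-induced carbonic anhydrase CA9 by 2.46 (SE 0.22). The 3 replicates of EPZ5676 lay outside the range of the 3 DMSO replicates in each of these genes, and each adjusted p was 1.21e-06 or lower.

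Transcripts of the sorted activity went in different directions in ALDH1+ cells. ALDH1A1 (ENSG00000165092.8), an enzyme of the ALDH1 class that oxidizes retinal, went from 33.1 ± 5.2 to 11.8 ± 2.1 CPM (log2 fold change -1.51, SE 0.15, adjusted p = 3.7e-06), and ALDH3A1 fell by 0.97 (SE 0.17, adjusted p = 5.4e-04). ALDH1A3 (ENSG00000184254.12), the most abundant of the 4 at 1640 ± 200 CPM in DMSO, rose by 0.25 (SE 0.08, adjusted p = 0.029), and ALDH1A2 rose by 0.42 (SE 0.15, adjusted p = 0.047). Both calls lay close to the threshold and were lost when any 1 of several libraries was left out. In these fits the log2 fold change stayed at 0.17 to 0.24 for ALDH1A3 and 0.26 to 0.41 for ALDH1A2. ALDH1A3 had adjusted p = 0.079 without DMSO replicate 1, 0.13 without DMSO replicate 3, 0.081 without EPZ5676 replicate 1 and 0.11 without EPZ5676 replicate 2. ALDH1A2 had adjusted p = 0.089 and 0.23 without DMSO replicates 1 and 3, and 0.19 and 0.074 without EPZ5676 replicates 2 and 3. Of 18 measured genes of the ALDH family, 5 rose and 9 fell, over all genes and adjusted over the list alone. They include ALDH3B2 at -1.71 (SE 0.12) and ALDH3B1 at 1.01 (SE 0.11). The list as a whole did not pass camera (adjusted p = 0.101). MYC fell by 0.52 (SE 0.07, adjusted p = 3.4e-05), and DOT1L (ENSG00000104885.13) itself had a log2 fold change of -0.11 (SE 0.09, adjusted p = 0.41).

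Gene lists that rose in ALDH1+ cells included mesenchymal, keratinocyte differentiation, basal, TGF-beta and YAP, and HOXA genes. Of 12 mesenchymal genes 10 rose and 1 fell, the same counts as adjusted over the list alone. They include FN1, the matrix protein fibronectin (3.85, SE 0.18, from 11.4 ± 2.6 to 162 ± 28 CPM), and the receptor kinase AXL (1.92, SE 0.14). The list passed camera with adjusted p = 1.0e-06 (adjusted p = 0.0935 with an estimated correlation). Of 24 keratinocyte differentiation genes 16 rose and 3 fell, or 18 and 3 adjusted over the list alone, including KRT13 (3.08, SE 0.16) and involucrin, IVL (1.13, SE 0.13). This list had adjusted p = 2.0e-06 by camera and adjusted p = 0.189 with an estimated correlation. Of 18 basal genes 9 rose and 3 fell on both adjustments, over all genes and adjusted over the list alone, among them the laminin chain LAMA3 (2.86, SE 0.11), with camera adjusted p = 0.00524 and adjusted p = 0.197 with an estimated correlation. Of 23 TGF-beta and YAP targets 10 rose and 1 fell (12 and 1 adjusted over the list alone, 14 and 3 with the replicate block). They had camera adjusted p = 8.47e-04 and adjusted p = 0.189 with an estimated correlation. Of 14 genes of the HOXA cluster and its MEIS and PBX cofactors 7 rose and 1 fell on both adjustments, over all genes and adjusted over the list alone. HOXA13 rose by 2.58 (SE 0.26) and HOXA10 by 1.45 (SE 0.11), and the list had camera adjusted p = 0.00172 (adjusted p = 0.0935 with an estimated correlation).

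Immune genes made up 3 of the lists that rose in ALDH1+ cells. Of 29 interferon-stimulated genes 17 rose and 2 fell (18 and 3 adjusted over the list alone), including IFIT2 (2.94, SE 0.25) and CMPK2 (1.89, SE 0.12). The list had camera adjusted p = 5.62e-05 and adjusted p = 0.0935 with an estimated correlation. Of 18 genes of MHC antigen presentation 12 rose and 1 fell, the same as adjusted over the list alone, with camera adjusted p = 2.34e-04 (adjusted p = 0.267 with an estimated correlation). HLA-B rose by 1.42 (SE 0.17) and the peptide transporter TAP2 by 0.77 (SE 0.09). Counts of single HLA genes are uncertain, because reads can be shared between them. Of 21 NF-kB and inflammatory genes 11 rose and 0 fell on both adjustments, over all genes and adjusted over the list alone (15 and 1 with the replicate block), including complement C3 (1.76, SE 0.14) and BIRC3 (0.94). Their mean level relative to the DMSO mean was 1.373, 0.989 and 0.466 in EPZ5676 replicates 1, 2 and 3. The DMSO libraries of the same numbers were at 0.309, -0.079 and -0.231. Both treatments thus had the same order of replicates, and part of the low value of replicate 3 was shared. This list had camera adjusted p = 0.00234 and adjusted p = 0.42 with an estimated correlation. Of 5 measured markers of other cell types 4 rose and 1 fell in the same comparison, with camera adjusted p = 0.138. The macrophage receptor CSF1R rose by 0.75 (SE 0.18) to 8.79 ± 1.1 CPM, collagen COL1A1 by 1.02 (SE 0.14) to 23.2 ± 2.2 CPM, and CD14 fell by 1.21 (SE 0.27) to 1.17 ± 0.39 CPM.

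Genes of sterol synthesis and of cell division fell. Of 25 cholesterol synthesis genes 21 fell and 0 rose (23 and 0 adjusted over the list alone), with a median log2 fold change of -0.63. The reductase DHCR7 fell by 1.08 (SE 0.09). This was the list with the smallest camera p (adjusted p = 1.46e-12), and its call held with an estimated correlation (adjusted p = 0.046 with an estimated correlation). Of 27 G2/M genes 26 fell and 0 rose, the same as adjusted over the list alone, with a median of -0.54. Their mean level relative to the DMSO mean was -0.625, -0.709 and -0.299 in EPZ5676 replicates 1, 2 and 3. The DMSO libraries of the same numbers were at -0.208, -0.026 and 0.234, so that replicate 3 was the highest in both treatments. The mitotic kinase AURKB fell by 0.94 (SE 0.18) and CDC20 by 0.54 (SE 0.11), and the list had camera adjusted p = 1.02e-08 and adjusted p = 0.326 with an estimated correlation. Of 24 DNA replication genes 9 fell and 1 rose (11 and 1 adjusted over the list alone, 15 and 1 with the replicate block), with camera adjusted p = 0.00478, adjusted p = 0.623 with an estimated correlation and 0.156 by fry. Their mean level relative to DMSO was -0.494, -0.359 and -0.045 in EPZ5676 replicates 1, 2 and 3, and -0.027 to 0.049 in the DMSO libraries, so that replicate 3 hardly moved. Of 40 ribosomal protein genes 10 fell and 0 rose over all genes, and 0 did when adjusted over the list alone, while 18 fell with the replicate block. Their median was -0.19, with camera adjusted p = 5.62e-05, adjusted p = 0.579 with an estimated correlation and 0.0974 by fry, and the libraries overlapped, at -0.27, -0.027 and -0.265 in EPZ5676 and -0.152 to 0.163 in DMSO.

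In total, edgeR called 5141 of 16327 genes in ALDH1+ cells, 2903 higher and 2238 lower in EPZ5676, at least 2-fold for 1194 and 237 of them. Groups did not overlap in 41.4% of genes, against 10% by chance. Lists lower at camera adjusted p from 0.0122 to 0.0265 were hypoxia and glycolysis, luminal genes and MYC targets, and each lost its call when 1 library was left out and with an estimated correlation (adjusted p = 0.267, 0.267 and 0.579). MYC targets had 0.105 by fry, and the levels of hypoxia genes overlapped between the groups. Without DMSO replicate 1 the p was 0.073 for luminal genes and 0.0754 for MYC targets, and without EPZ5676 replicate 3 it was 0.0913 for hypoxia and 0.0939 for MYC targets. MYC targets were also lost without EPZ5676 replicate 2, at 0.052, and luminal genes with the replicate block, at 0.0776.

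**Figure D2:**
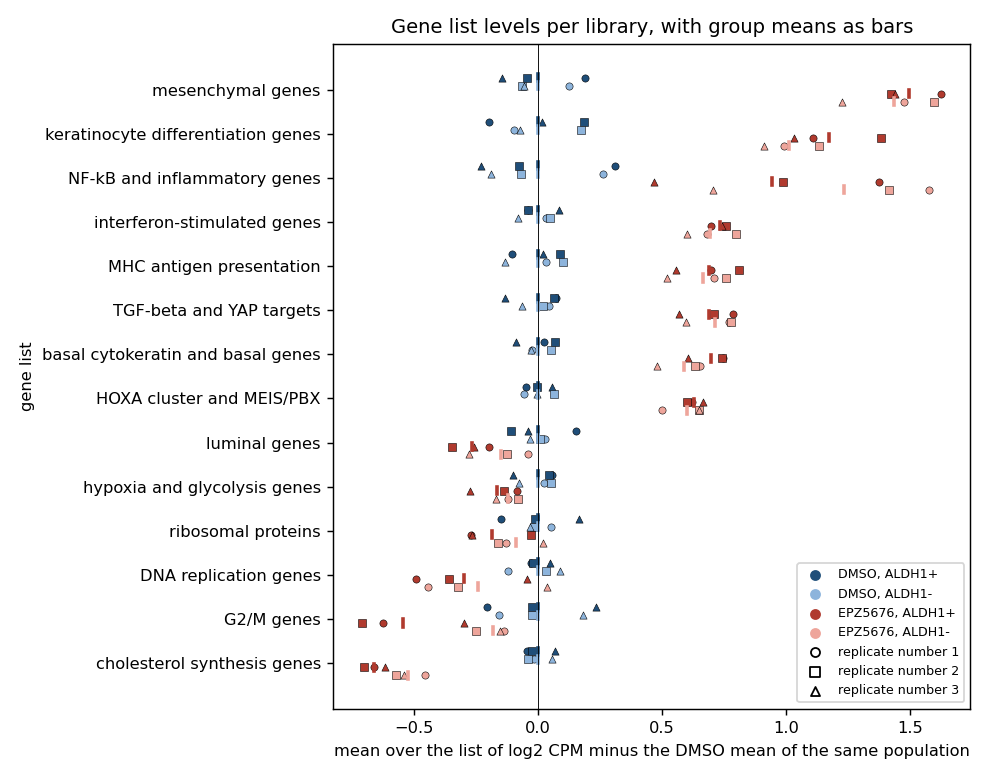
Level of 14 gene lists in each library, as the mean over the list of log2 CPM minus the DMSO mean of the same population (horizontal axis), with points for libraries and bars for group means (n = 3). G2/M genes lie at -0.709 to -0.299 in the EPZ5676 ALDH1+ libraries and at -0.251 to -0.136 in the EPZ5676 ALDH1- libraries.

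The same treatment was compared in ALDH1- cells. PRR9 went from 0.693 ± 0.28 to 22.3 ± 2.6 CPM (SD, n = 3; log2 fold change 4.99, SE 0.32, adjusted p = 1.7e-07). SPRR3 rose by 4.23 (SE 0.34), HEPHL1, a ferroxidase, by 4.26 (SE 0.36), GREM1 by 4.03 (SE 0.29), and SERPINB2, the plasminogen activator inhibitor PAI-2, by 3.70 (SE 0.48). SPRR3 in DMSO ALDH1- replicate 1, at 0.0733 CPM, lay below the level of 3 counts in that library, 0.11 CPM. ATP13A5 fell by 3.74 (SE 0.29), EN1 by 2.82 (SE 0.19) and SYT12 by 2.35 (SE 0.17). ALDH1A1 went from 25.3 ± 2.9 to 12 ± 1.8 CPM (-1.08, SE 0.15, adjusted p = 1.4e-04) and ALDH3A1 fell by 1.06 (SE 0.18), while ALDH1A3 had a log2 fold change of 0.08 (SE 0.08, adjusted p = 0.53) and ALDH1A2 of 0.19 (SE 0.15, adjusted p = 0.41). MYC fell by 0.43 (SE 0.07). DOT1L had a log2 fold change of -0.25 (SE 0.10, adjusted p = 0.079), and was called with the replicate number as a block (adjusted p = 0.014).

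The lists that rose in ALDH1- cells were mesenchymal, keratinocyte differentiation, basal, TGF-beta and YAP, HOXA, interferon, MHC, and NF-kB genes. Of 12 mesenchymal genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), with FN1 up by 3.63 (SE 0.18). They had camera adjusted p = 1.33e-07, and adjusted p = 0.0636 with an estimated correlation. Of 21 NF-kB and inflammatory genes 11 rose and 0 fell (16 and 0 adjusted over the list alone, 17 and 0 with the replicate block), with C3 up by 1.73. They had camera adjusted p = 2.51e-06 and adjusted p = 0.225 with an estimated correlation. Of 29 interferon-stimulated genes 17 rose and 0 fell (18 and 0 adjusted over the list alone), with IFIT2 up by 2.21 (SE 0.24). This list had camera adjusted p = 4.27e-06 and adjusted p = 0.0541 with an estimated correlation. Of 24 keratinocyte differentiation genes 14 rose and 2 fell, or 17 and 2 adjusted over the list alone, with KRT13 up by 2.95 (SE 0.18); camera gave adjusted p = 5.34e-07, and adjusted p = 0.141 with an estimated correlation. Over all genes, 12 of 18 MHC genes (14 adjusted over the list alone), 12 of 23 TGF-beta and YAP targets (15 adjusted over the list alone), 7 of 14 HOXA genes (8 adjusted over the list alone) and 8 of 18 basal genes (8 adjusted over the list alone) rose. Their camera adjusted p were 5.78e-05, 1.22e-04, 2.36e-04 and 0.00776, and adjusted p = 0.232, 0.113, 0.0541 and 0.186 with an estimated correlation. Of the 5 markers of other cell types 3 rose and 0 fell, with camera adjusted p = 0.0705. They include the leukocyte antigen PTPRC, which rose by 2.06, from 0.169 ± 0.015 to 0.713 ± 0.21 CPM. Its DMSO level was close to that of 3 counts in these libraries, 0.102 to 0.115 CPM, so its fold is imprecise.

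Cholesterol synthesis genes fell in ALDH1- cells as well, 21 of 25 over all genes and 22 adjusted over the list alone, with a median of -0.51. The list had camera adjusted p = 1.27e-10 and adjusted p = 0.0541 with an estimated correlation. The G2/M list was lower with a median of -0.20 and camera adjusted p = 0.027, adjusted p = 0.723 with an estimated correlation and 0.316 by fry. The libraries overlapped, at -0.251 to -0.136 in EPZ5676 and -0.158 to 0.182 in DMSO. Over all genes 1 of its 27 genes, MKI67, fell (-0.51, SE 0.17, adjusted p = 0.044), and 0 did adjusted over the list alone. Without DMSO replicate 2 or 3 its adjusted p was 0.11 or 0.22, and without EPZ5676 replicate 1, 2 or 3 it was 0.11, 0.097 or 0.1. With the replicate number as a block 11 fell and 1 rose, and AURKB, at -0.46 (SE 0.18, adjusted p = 0.077), was among those called (adjusted p = 8.7e-04). The call on the G2/M list was lost without DMSO replicate 3 (adjusted p = 0.197) and without EPZ5676 replicate 2 (adjusted p = 0.0718).

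ALDH family genes were lower as a list in ALDH1- cells, with 9 of 18 lower and 2 higher over all genes and 10 and 2 adjusted over the list alone. Camera gave adjusted p = 0.023, with adjusted p = 0.141 with an estimated correlation and 0.0523 without DMSO replicate 1. In total 3695 genes were called in ALDH1- cells, 2219 higher and 1476 lower, at least 2-fold for 970 and 144. With the replicate block 2837 were higher and 2423 lower. The number lower was 904 and 900 without DMSO replicates 2 and 3, and 891 and 942 without EPZ5676 replicates 1 and 2. Groups did not overlap in 39.1% of genes, against 10% by chance. Lists lower at camera adjusted p from 0.00746 to 0.0381 that lost the call when 1 library was left out were DNA replication, ribosomal protein, luminal, NRF2 and hypoxia genes. With an estimated correlation their adjusted p were 0.669, 0.786, 0.309, 0.232 and 0.338, and by fry DNA replication genes had 0.208 and ribosomal protein genes 0.4. DNA replication genes lay at -0.444, -0.324 and 0.037 relative to the DMSO mean in EPZ5676 replicates 1, 2 and 3. Ribosomal protein genes lay at -0.128, -0.163 and 0.018, so that replicate 3 was not below the DMSO mean in either list. In DMSO replicate 3 the lists were at 0.09 and -0.033. Without EPZ5676 replicate 1 the p rose to 0.0773 for DNA replication, 0.0605 for NRF2 and 0.0773 for ribosomal protein genes. Without DMSO replicate 1 it was 0.0666 for hypoxia, 0.0503 for luminal, 0.0869 for NRF2 and 0.128 for ribosomal protein genes. Luminal and hypoxia genes were also lost without DMSO replicate 2 (0.0556 and 0.0629), luminal genes without EPZ5676 replicate 3 (0.117) and with the replicate block (0.112), and ribosomal protein genes without EPZ5676 replicate 2 (0.176).

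Most genes called in either population changed in the same direction in both. Of the genes called, 1971 rose in both populations and 1082 fell in both, against 394.5 and 202.3 for independent sets of those sizes. With the replicate block 2524 genes rose in both, against 629.9, and 1828 fell in both, against 474.2. Only EFEMP1, named after its values were seen, was called in opposite directions without the block (2 genes were with it), at -0.286 (adjusted p = 0.0371) in ALDH1+ and 0.291 (adjusted p = 0.0465) in ALDH1- cells. Its call in ALDH1+ was lost without DMSO replicate 1 (0.12) or 3 (0.08) or EPZ5676 replicate 1 (0.12) or 2 (0.15). In ALDH1- it was lost without DMSO replicate 1 (0.15), 2 (0.058) or 3 (0.1) or EPZ5676 replicate 2 (0.17) or 3 (0.078). Of 5782 genes called in either population 5665 had the same sign in both. The Pearson correlation of log2 fold changes across genes was 0.892, over genes that are not independent replicates. The comparisons share no library, but libraries of the same number varied together across the populations. Their deviations correlated at 0.65, 0.17 and 0.57 in EPZ5676 and at 0.39, 0.3 and 0.32 in DMSO for numbers 1, 2 and 3. The 2 comparisons are therefore not independent of each other.

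**Figure D3:**
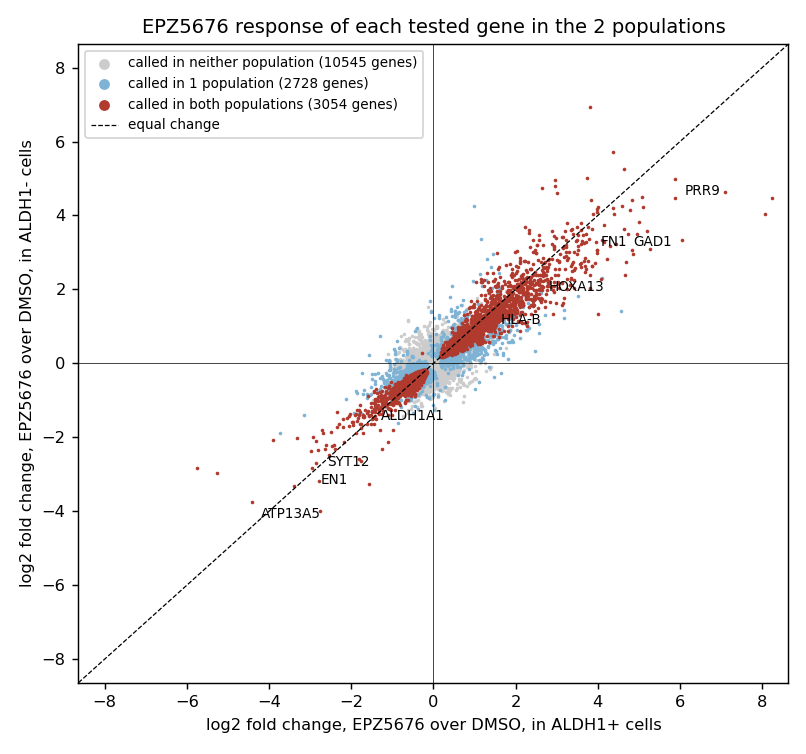
Log2 fold change, EPZ5676 over DMSO, in ALDH1+ (horizontal axis) and ALDH1- cells (vertical axis), with 1 point per gene. Of the genes tested, 3054 were called in both populations, 2728 in 1 and 10545 in neither, and the correlation across genes was 0.892.

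Averaged over both populations, LAMA3 had the smallest p (2.59, SE 0.08, adjusted p = 4.1e-11), PRR9 rose by 5.44 (SE 0.22), FN1 by 3.74 (SE 0.13) and GAD1 by 4.13 (SE 0.14), and EN1 fell by 2.89 (SE 0.13). ALDH1A1 fell by 1.3 (SE 0.11, adjusted p = 2.4e-07) and ALDH3A1 by 1.01 (SE 0.12). ALDH1A3 rose by 0.17 (SE 0.06, adjusted p = 0.031) and ALDH1A2 by 0.30 (SE 0.11, adjusted p = 0.034). MYC fell by 0.48 (SE 0.05) and DOT1L by 0.18 (SE 0.07, adjusted p = 0.045). The averaged calls of DOT1L, ALDH1A2 and ALDH1A3 were close to the threshold. Without ALDH1+ DMSO replicate 1 their adjusted p were 0.11, 0.054 and 0.063, without ALDH1- DMSO replicate 2 0.12, 0.066 and 0.064, without ALDH1- DMSO replicate 3 0.06, 0.063 and 0.055, and without ALDH1+ EPZ5676 replicate 2 0.072, 0.092 and 0.068. Calls of DOT1L were also lost without ALDH1+ DMSO replicate 2 (0.073), ALDH1+ EPZ5676 replicates 1 (0.07) and 3 (0.072), and ALDH1- EPZ5676 replicates 1 (0.057) and 3 (0.11). ALDH1A2 was lost without ALDH1+ DMSO replicate 3 (0.085) and ALDH1- EPZ5676 replicates 1 (0.073) and 2 (0.086), and ALDH1A3 without ALDH1+ DMSO replicate 3 (0.064), ALDH1- DMSO replicate 1 (0.054), ALDH1+ EPZ5676 replicate 1 (0.057) and ALDH1- EPZ5676 replicate 3 (0.059). Of 27 G2/M genes 26 fell and 0 rose, the same as adjusted over the list alone, with a median of -0.36 (camera adjusted p = 5.39e-06, and adjusted p = 0.448 with an estimated correlation). Of 25 cholesterol synthesis genes 22 fell (23 adjusted over the list alone), with camera adjusted p = 2.11e-11 and adjusted p = 0.0616 with an estimated correlation. Of 18 retinoic acid targets 9 rose and 9 fell, and the list had camera adjusted p = 0.956. The test called 6846 genes, 3579 higher and 3267 lower.

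The interaction asks whether EPZ5676 acted differently in the 2 populations. No gene was called by edgeR, although 597 had an unadjusted p under 0.05; the smallest adjusted p was 0.979, and DESeq2, limma-voom and the block also called 0. Without the filter on low counts 37 were called, in a fit whose p-values were far smaller for well-expressed genes too. The log2 difference between populations was -0.43 (SE 0.21) for ALDH1A1, 0.17 (SE 0.11) for ALDH1A3, 0.22 (SE 0.22) for ALDH1A2, 0.09 (SE 0.25) for ALDH3A1, -0.09 (SE 0.09) for MYC and 0.14 (SE 0.13) for DOT1L, each with an adjusted p of 0.98. The G2/M list was lower in the interaction, with a median of -0.34 and 0 of 27 genes above 0. Its camera adjusted p was 3.68e-13, and adjusted p = 0.754 with an estimated correlation. No single G2/M gene was called, over all genes or adjusted over the list alone.

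Cells sorted by ALDH1 activity were next compared within DMSO. ALDH1A3 was at 1640 ± 200 CPM in ALDH1+ and 1370 ± 9.3 CPM in ALDH1- cells (SD, n = 3), a log2 fold change of 0.26 (SE 0.08, adjusted p = 0.17, and 0.042 with the replicate number as a block). ALDH1A1 was at 33.1 ± 5.2 and 25.3 ± 2.9 CPM (0.40, SE 0.15, adjusted p = 0.20, and 0.025 with the block). ALDH1A2 had a log2 fold change of -0.10, ALDH3A1 of 0.16 and MYC of 0.03, and DOT1L of -0.21 (SE 0.09, adjusted p = 0.26). With the block, genes were named after its values were seen, by the naming rule with pairs of equal number that all move the same way in place of groups that do not overlap. Genes higher in ALDH1+ cells included the keratins KRT13 (1.01, SE 0.18), KRT14 (0.80, SE 0.09) and KRT16 (0.64, SE 0.09) and CA9 (0.87, SE 0.15). Lower in ALDH1+ were the heat shock genes HSPA6 (-4.28, SE 0.48, adjusted p = 8.4e-04) and CRYAB (-1.60, SE 0.18), the stress-induced gene NIBAN1 (-1.39, SE 0.16) and the glycoprotein hormone subunit CGA (-1.66, SE 0.29). Without the block HSPA6 had -4.59, CRYAB -1.72 and CGA -1.93, and -3.42, -1.11 and -0.97 when ALDH1- replicate 1 was also left out. HSPA6 in ALDH1+ replicate 2, at 0.0797 CPM, lay below the level of 3 counts in that library, 0.118 CPM. KRT14, KRT16 and HSPA6 have close copies with which reads can be shared.

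By edgeR without the block 0 genes differed between populations in DMSO, with 2904 at an unadjusted p under 0.05 and a smallest adjusted p of 0.161. DESeq2 called 298, limma-voom 0, and the replicate block 1384, of which 564 were higher and 820 lower in ALDH1+. Without ALDH1- replicate 2 edgeR called 1 gene. Groups did not overlap in 23.1% of genes, against 10% by chance. Ribosomal protein genes were higher in ALDH1+ (median 0.23, camera adjusted p = 6.27e-14, and adjusted p = 0.627 with an estimated correlation), with 0 called over all genes (4 with the block) and 29 of 40 adjusted over the list alone. Keratinocyte differentiation genes were also higher (median 0.27, camera adjusted p = 0.00105, and adjusted p = 0.549 with an estimated correlation), with 0 called over all genes (7 higher and 1 lower with the block), and 8 higher and 1 lower adjusted over the list alone. The ALDH family as a list did not differ (adjusted p = 0.729). Interferon genes were lower in ALDH1+ (median -0.10, adjusted p = 0.0298, and adjusted p = 0.524 with an estimated correlation), a call lost with the block (0.0643) and without DMSO ALDH1+ replicate 1 (0.129), ALDH1- replicate 1 (0.074) or ALDH1- replicate 2 (0.0703).

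In EPZ5676 3 genes differed between populations, all of them keratinocyte differentiation genes and all higher in ALDH1+ cells. SPRR3 was at 13 ± 2.9 against 4.14 ± 0.49 CPM (3.16-fold, log2 fold change 1.66, SE 0.20, adjusted p = 0.0047), SPRR1B at 12.6 ± 2.0 against 5.67 ± 0.62 CPM (2.22-fold, adjusted p = 0.0047) and KRT13 at 18.8 ± 2.7 against 8.73 ± 0.79 CPM (2.16-fold, adjusted p = 0.0056). Without ALDH1+ replicate 2 their adjusted p were 0.053, 0.053 and 0.068, and without ALDH1- replicate 2 each was 0.061. SPRR genes resemble each other, so that reads may be counted for the wrong member. ALDH1A3 was at 1950 ± 120 and 1450 ± 54 CPM (0.43, SE 0.08, adjusted p = 0.16, and 0.016 with the block), and ALDH1A1 at 11.8 ± 2.1 and 12 ± 1.8 CPM (-0.03, SE 0.16, adjusted p = 0.98). MYC had a log2 fold change of -0.06 and DOT1L of -0.08. With the block 75 genes were called, 31 higher and 44 lower, and the naming rule used for the block gave KRT14 (0.91, SE 0.09), PRR9 (1.09, SE 0.15) and the interleukin-1 antagonist IL1RN (0.74, SE 0.09) among the higher and CRYAB (-2.08, SE 0.18) and HSPA6 (-3.13, SE 0.42) among the lower genes.

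At the level of lists, keratinocyte differentiation genes were higher in ALDH1+ cells under EPZ5676 (median 0.22, camera adjusted p = 6.9e-08, and adjusted p = 0.498 with an estimated correlation), with 3 higher and 0 lower over all genes, 9 and 1 adjusted over the list alone, and 7 and 1 over all genes with the block. G2/M genes were lower (median -0.26, camera adjusted p = 3.18e-12, and adjusted p = 0.502 with an estimated correlation), with 0 called over all genes and 4 lower adjusted over the list alone. Unadjusted, 1032 genes had p under 0.05, and DESeq2 called 31 and limma-voom 3. The count of called genes was 0 without ALDH1+ replicate 2 or ALDH1- replicate 2, 10 without ALDH1+ replicate 3 and 21 without ALDH1- replicate 3. Groups did not overlap in 9.6% of genes, against 10% by chance.

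Averaged over both treatments, a comparison added after the data were seen, the heat shock genes HSPA6 and CRYAB and some keratinocyte genes differed between the populations. HSPA6, a stress-inducible HSP70, was 14.8-fold lower in ALDH1+ (log2 fold change -3.89, SE 0.47, adjusted p = 0.0053; -3.30 without DMSO ALDH1- replicate 1), at 0.338 ± 0.23 against 8.82 ± 8.5 CPM in DMSO and 0.726 ± 0.11 against 6.64 ± 3.0 CPM in EPZ5676. The small heat shock protein CRYAB was 3.74-fold lower (-1.90, SE 0.24, adjusted p = 0.0053). KRT13 (1.04, SE 0.12), SPRR1B (0.85, SE 0.11), KRT14 (0.83, SE 0.14) and KRT16 (0.70, SE 0.10) were higher in ALDH1+ cells. ALDH1A3 was higher by 0.35 (SE 0.06, adjusted p = 0.037) and ALDH1A1 had a log2 fold change of 0.18 (adjusted p = 0.37). Of 24 keratinocyte differentiation genes 3 were higher and 1 was lower over all genes, 11 and 1 adjusted over the list alone, and 10 and 1 with the replicate block (camera adjusted p = 8.06e-07, and adjusted p = 0.419 with an estimated correlation). With the block the adjusted p of ALDH1A3, KRT14 and KRT16 were 0.0023, 3.6e-06 and 2.7e-05. Without it these 3 calls were lost when ALDH1+ DMSO replicate 2 (0.079, 0.12 and 0.074), ALDH1- DMSO replicate 2 (0.084, 0.084 and 0.055), ALDH1+ EPZ5676 replicate 2 (0.11, 0.12 and 0.062) or ALDH1- EPZ5676 replicate 2 (0.17, 0.17 and 0.095) was left out. ALDH1A3 and KRT14 were also lost without ALDH1- DMSO replicate 1 (0.11 for both) or ALDH1- EPZ5676 replicate 1 (0.13 for both), ALDH1A3 without ALDH1- DMSO replicate 3 (0.061) or ALDH1+ EPZ5676 replicate 1 (0.057), and KRT14 without ALDH1+ DMSO replicate 3 (0.089).

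The averaged comparison of populations called 26 genes, 10 higher and 16 lower in ALDH1+, and 1993 with the replicate block, 948 higher and 1045 lower, which kept all 26. Of the calls 38.5% were higher, against 23.5% of 34 with total counts as library sizes, 47.6% with the block, 59.2% of 755 without the EPZ5676 libraries numbered 3, 60.5% of 1238 without a filter and 64.2% of 721 by DESeq2, so that the balance of directions depends on the setting. The count without the block rests on single libraries. Without DMSO ALDH1+ it was 453, 5 and 9 for replicates 1, 2 and 3, and without DMSO ALDH1- 7, 6 and 16. Without EPZ5676 ALDH1+ it was 15, 4 and 163, and without EPZ5676 ALDH1- 6, 5 and 708. Thinning all libraries to the same depth left 7 calls without the block and 1772 with it.

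**Figure D4:**
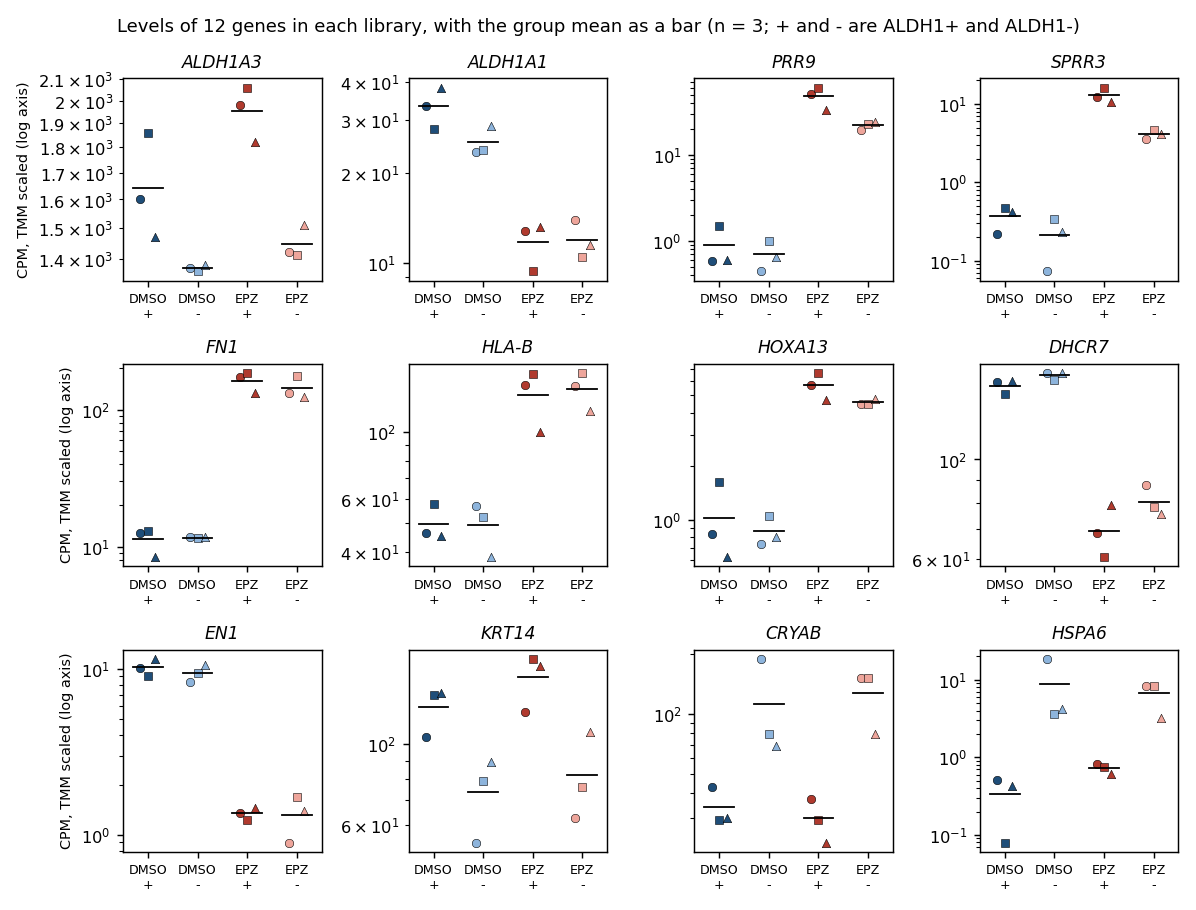
Levels in CPM (log axis) of 12 genes in each of the 4 groups, with points for the 3 libraries and a bar for the group mean. PRR9, SPRR3, FN1 and HOXA13 lie higher and DHCR7, EN1 and ALDH1A1 lower in EPZ5676 than in DMSO, and HSPA6 and CRYAB lie higher in ALDH1- than in ALDH1+ cells.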

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

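In this part the splits that count genes were chosen after the result was seen, and the splits that count gene lists before. A difference between the populations in the response to EPZ5676 was the reason to look again at 6 gene lists, each by camera on the interaction. G2/M genes had a lower log2 fold change with EPZ5676 in ALDH1+ than in ALDH1- cells, by a median of -0.34 with 0 of 27 genes above 0 (adjusted p = 3.68e-13). The call held when any 1 library was left out, but was lost with an estimated correlation and by fry. Their mean log2 level relative to DMSO was -0.625, -0.709 and -0.299 in EPZ5676 ALDH1+ replicates 1, 2 and 3, and -0.136, -0.251 and -0.155 in EPZ5676 ALDH1-. The DMSO libraries of the same list spread from -0.208 to 0.234, with the lowest values in replicates 1 and the highest in replicates 3 of both populations. Ribosomal protein genes differed by a median of -0.09 (adjusted p = 0.00111), a call lost without DMSO ALDH1+ replicate 3 (0.329), EPZ5676 ALDH1+ replicate 1 (0.0592) or 3 (0.12), or EPZ5676 ALDH1- replicate 3 (0.125). Cholesterol synthesis genes differed by a median of -0.09 (adjusted p = 0.00542), lost without EPZ5676 ALDH1- replicate 1 (0.111). NF-kB and inflammatory genes differed by -0.17 (adjusted p = 0.0218), lost without DMSO ALDH1+ replicate 1 (0.394), DMSO ALDH1- replicate 3 (0.237), EPZ5676 ALDH1+ replicate 3 (0.534), or EPZ5676 ALDH1- replicate 1 (0.261) or 2 (0.207). ABC transporters differed by 0.23 (adjusted p = 0.0218), lost without DMSO ALDH1+ replicate 3 (0.305), DMSO ALDH1- replicate 1 (0.139), EPZ5676 ALDH1+ replicate 1 (0.0592) or EPZ5676 ALDH1- replicate 3 (0.201). Immediate early genes differed by -0.13 (adjusted p = 0.0487), lost with RLE scaling (0.056), without DMSO ALDH1+ replicate 1 (0.439) or 2 (0.0726), DMSO ALDH1- replicate 3 (0.587), EPZ5676 ALDH1+ replicate 2 (0.0896) or 3 (0.534), or EPZ5676 ALDH1- replicate 1 (0.683) or 2 (0.136).

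With an estimated correlation between genes the 6 lists had an adjusted p of 0.754 to 0.79 in the interaction, and fry gave 0.8 for each. Of 100 splits of the 12 libraries, 44 called at least the 6 lists of the real split, and the highest other called 13, so that chance is not excluded for the number of lists. For genes, the interaction called 0 in the real split and all 100 splits had at least that many, up to 1866.

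Splits of the other comparisons gave the following. In ALDH1+ cells EPZ5676 called 5141 genes and 15 lists, against at most 38 genes and 10 lists in the other splits. In ALDH1- cells it called 3695 genes and 16 lists, against at most 0 genes and 13 lists. These designs have 10 splits each, too few for a share under 0.05, and 1 of 10, the real one, was as large in each case. The populations in DMSO gave 0 genes and 6 lists, against at most 0 and 8, with 10 and 2 of 10 splits as large. In EPZ5676 they gave 3 genes and 9 lists, against at most 7 and 9, with 2 of 10 splits as large for both, and these designs are likewise too small. For the treatment averaged over both populations 1 of 100 splits had as many as 6846 genes (highest other 3831), and 2 of 100 had as many as 15 lists (highest other 15). For the populations averaged over both treatments 2 of 100 splits had as many as 26 genes (highest other 1121), a count that ranged from 4 to 708 when 1 library was left out, and 42 of 100 had as many as 6 lists (highest other 14), so that chance is not excluded for lists. Taken over all 100 splits, the other 3 shares lie under 0.05. The replicate numbers pair the libraries, however, and only 16 of the 100 splits part all pairs of equal number as the real ones do, too few for a share under 0.05. Among these the real split alone called any gene in either averaged comparison, and the highest other number of lists was 13 for the treatment.

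The other splits that called many genes keep at least 1 pair of equal number together, but so do most splits that called 0 genes. The split with 3831 genes kept every ALDH1+ library in its treatment and exchanged DMSO replicate 1 with EPZ5676 replicate 3 in ALDH1- cells. The split with 1121 genes set all libraries numbered 3 and ALDH1+ replicates 2 against all numbered 1 and ALDH1- replicates 2, and that with 1866 genes in the interaction had the same sides within EPZ5676 and the real populations within DMSO. Calls by splits that part numbers 1 and 3 point to a structure of the samples by replicate number, and its cause was not tested. With the number as a block the real populations differed in 1993 genes.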

How the results depend on the processing

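Chosen after the data were seen were thinning, leaving out both EPZ5676 libraries numbered 3, the block with thinning, and the comparison of populations averaged over treatments. The total treatment counts, in either population and averaged, stayed within 1.5 times under every setting, but in ALDH1- the 1476 lower genes became 2423 with the block and 891 to 942 without DMSO replicate 2 or 3 or EPZ5676 replicate 1 or 2. The counts between populations did not, and the cause was not tested unless stated. Without a filter they were 948 in DMSO, 235 in EPZ5676 and 1238 averaged, and 37 for the interaction. In that fit p-values were far smaller for well-expressed genes too, at nearly the same folds. Between populations in DMSO, KRT14 had adjusted p = 1.0e-16 at 0.8 and CRYAB 1.5e-72 at -1.7, against 0.16 for both in the main fit. The added calls without a filter are therefore not taken as evidence of further differences. DESeq2 called 298, 31 and 721. The replicate block called 1384, 75 and 1993, removing variation shared by libraries of 1 number, and 1328, 72 and 1772 with thinning. Without the EPZ5676 libraries numbered 3 the counts were 3, 13 and 755; thinning left 7 averaged, and a fit of the EPZ5676 groups alone called 5. Genes lower in both populations with EPZ5676 numbered 1828 with the block. Leaving out 1 library gave 3793 to 5450 calls for EPZ5676 in ALDH1+, 2604 to 3652 in ALDH1- and 5989 to 7083 averaged. Between populations it gave 0 to 1 in DMSO, 0 to 21 in EPZ5676 and 4 to 708 averaged, and 0 to 0 for the interaction.

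Lists called with an estimated correlation were 1 for EPZ5676 in ALDH1+ and 0 in the 6 other comparisons. fry called 22 in ALDH1+, 19 in ALDH1- and 23 averaged, and between populations 1 in DMSO, 0 in EPZ5676 and 1 averaged, and 0 for the interaction. Without 1 library lists ranged from 13 to 16, 11 to 16 and 12 to 17 for the treatment, 4 to 8, 4 to 11 and 5 to 7 between populations, and 3 to 8 for the interaction. The 73 list calls under 965 alternatives kept call and direction in 760, lost the call in 205 and reversed in 0. The 125 results on named genes under 2324 alternatives were unchanged in 2156, lost the call in 90, gained it in 78 and reversed in 0. Unchanged includes genes that were called neither in the main fit nor in the alternative, and their direction was not compared. All 132 alternatives of the interaction are of this kind. The 0 reversals of genes therefore cover only genes called in the main fit, the alternative or both. For lists they cover only those called in both fits. RLE scaling changed no call among the 125 results. With the block luminal genes lost their call for the averaged treatment too (0.125). It gained calls between the populations for the DOT1L complex (0.0468) and G2/M genes (0.0416) in DMSO, for immediate early genes in EPZ5676 (1.2e-04), and for NRF2 targets, ABC transporters and NF-kB genes averaged over treatments (0.0442 each). Beyond these and the blocked values in the report, the block changed no other call of a list or named gene. Alternatives for normalized values, such as another pseudocount, did not apply, because the deposited values are counts. Depth limits what can be said of genes near 3 counts.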

Other observations

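In this part all groups of genes by symbol, the split by population of the tests on the libraries numbered 3, the genes named in the first paragraphs, ARC and EGR4, and the heat shock targets with HSPA6 and CRYAB included were chosen after the result was seen; with both populations together the tests on the libraries numbered 3 had left both explanations open, and the split also made the bound for a shared shift stricter, by applying it to the lower end of the interval. The other tests were written down before their result. Genes were grouped by the stem of their symbol, which gave 199 families of at least 10 members among 14869 named genes, of which 22.7% rose and 20.9% fell with EPZ5676 averaged over both populations. Interleukins and their receptors rose more often than other genes, 26 of 45 (Fisher's exact test, adjusted p = 2.6e-05). IL6 rose by 2.67 (SE 0.34), from 0.588 to 3.71 CPM, the receptor gene IL7R by 2.01 (SE 0.17), from 6.16 to 24.8 CPM, and the common gamma chain IL2RG by 2.71 (SE 0.34), while IL22RA2 fell by 1.70 (SE 0.14). Collagens rose in 16 of 24 (adjusted p = 1.5e-04). The basement membrane chains COL4A1 and COL4A2, which lie next to each other in the genome, rose by 2.31 (SE 0.08) and 2.27 (SE 0.07), and COL17A1, a hemidesmosome collagen, by 2.52 (SE 0.13). Clade B serpins rose in 10 of 12 (adjusted p = 3.7e-04). SERPINB2 went from 16.7 to 222 CPM (3.73, SE 0.33), SERPINB7 rose by 1.33 (SE 0.13) and SERPINB5 (maspin) by 0.93 (SE 0.06). Integrin beta symbols, which take in antisense and binding partner genes, rose in 9 of 14 (adjusted p = 0.017), with ITGB4 up by 1.04 (SE 0.05) and ITGB2 by 1.62 (SE 0.09), and ITGB6 down at -0.45 (SE 0.07). Family members can share reads, and they are not independent of each other.

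Long noncoding RNAs of the LINC stem also rose more often than the background, 86 of 237 or 36.3% (adjusted p = 1.1e-04), as did solute carriers of the SLC stem, 92 of 260 or 35.4% (adjusted p = 1.2e-04). Other families rose less often. Zinc finger genes of the ZNF stem rose in 43 of 509 and fell in 87 (adjusted p for rises = 1.9e-15), although ZNF365 rose by 2.01 (SE 0.09) and ZNF462 by 1.92 (SE 0.13). Mitochondrial ribosomal proteins of the MRPL stem rose in 0 of 50 and fell in 14 (adjusted p for rises = 1.3e-04), and translation initiation factors of the EIF stem rose in 5 of 66 (adjusted p = 0.024). None of the family tests took the level of the genes into account. Of the 3266 tested genes with the lowest DMSO levels 1062 rose, and of the 3266 with the highest levels 473 rose. The tests therefore do not separate a family from the level of its genes. No family had more or fewer falls than the background at an adjusted p under 0.05; the smallest, 0.098, was shared by the AKR (8 of 12 fell), ALDH (10 of 18) and NUP (12 of 24) stems.

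The populations differed in the heat shock genes HSPA6 and CRYAB and in the keratins KRT13, KRT14 and KRT16. A heat shock in the ALDH1- sort is argued against by 18 other heat shock factor targets, a list that left out HSPA6 and CRYAB. Their median log2 difference between ALDH1+ and ALDH1- was 0.13 (bootstrap interval 0.06 to 0.15), so they lay slightly higher in ALDH1+, from -0.07 to 0.47, and of the 5 called with the replicate block 0 were higher in ALDH1-. With both genes included the median of 20 was 0.11 (interval 0.03 to 0.14), but 2 genes can hardly move such a median, so this adds no support. These targets do not test other handling stress, which stays open. Immediate early and sorting stress genes had a median of -0.09 (camera adjusted p = 0.638, 0.0602 with the block, and 0.889 with an estimated correlation), and with the block 6 of 25 were lower and 1 was higher in ALDH1+. In EPZ5676 the list was lower in ALDH1+ with the block (1.2e-04, against 0.0514 without it, 0.682 with an estimated correlation and 0.686 by fry), and the immediate early genes ARC (-1.23, adjusted p = 0.0071) and EGR4 (-1.16, 0.011), averaged over treatments with the block (0.12 and 0.28 without it), go with such a stress. The greater depth of a pair of ALDH1+ libraries is argued against as well, since after thinning 84.4% (interval 82.8 to 86.0) of 1993 genes called with the block were still called. Without the block 7 of 26 calls were kept, among them HSPA6 (-3.94, SE 0.51, against -3.89, SE 0.47, before thinning), CRYAB (-1.92, SE 0.24, against -1.90, SE 0.24) and KRT13 (1.03, SE 0.12, against 1.04, SE 0.12). KRT14 lost its call (0.052) at 0.84 (SE 0.14) against 0.83 (SE 0.14), and ALDH1A3 (0.05) at 0.35 (SE 0.06) in both, so that their adjusted p passed the threshold while fold and SE moved little. A difference in the biology of the sorted populations, and effects of the sort on these genes alone, stay open and were not tested.

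The EPZ5676 libraries numbered 3 lay closer to DMSO than the other EPZ5676 libraries. In ALDH1+ cells a mixture with DMSO-treated cells or RNA would lower strongly induced genes by about the same share, but the loss in replicate 3 grew with the induction in replicate 1, with a slope of 0.29 over 340 genes (interval 0.21 to 0.37). The same genes were lower in DMSO replicate 3 than in DMSO replicate 2 by a median of 0.31 (interval 0.24 to 0.37), against a loss of 0.39 in EPZ5676, which is consistent with a shift of replicate 3 that both treatments share. In ALDH1- cells the slope was 0.13 over 286 genes (interval 0.02 to 0.26), the DMSO difference 0.19 (interval 0.10 to 0.31) and the loss 0.41. By these tests a mixture and a shared shift cannot be told apart there, because both intervals reach across the bounds set for them. On the first principal component the DMSO ALDH1- library numbered 3 was also the lowest of its group, at -39.1 against -26.3 and -32.4. In DMSO ALDH1+ number 3 was at -47.4 against -37.6 and -37. A shift shared by both treatments goes with these positions, which rest on 1 library per group. No biological explanation was tested.

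Genes at a low level in DMSO rose far more often than they fell. In the lowest quintile of DMSO levels, 0.015 to 1.18 CPM, 1062 genes rose and 159 fell over both populations, which is 87.0% rises, against 31.8% in the highest quintile. More genomic DNA in the EPZ5676 libraries is argued against, as far as their sum goes, by 114 olfactory receptor genes, silent in most cells. Their summed level was 22.1 CPM in DMSO and 18.6 CPM in EPZ5676, a ratio of 0.84 (interval 0.77 to 1.29). A sum gives most weight to the genes with the most counts, so a thin background at silent genes is tested only weakly. In the lowest quintile the share of rises was 88.2% after thinning and at least 87.1% under other scalings. These genes were picked by a low DMSO level after a filter that expression in EPZ5676 alone could pass, which favours rises. TMM factors of 0.975 to 1.021 also left scaling little room, so these shares do not decide on depth or scaling. Without a filter, 83.8% rose in the lowest quintile of mean level among called genes. This argues against the ranking by DMSO level as the only source, though that fit gave far smaller p-values for some genes. A larger share of unspliced RNA, which silent genes do not test, and a release of almost silent genes by loss of DOT1L activity stay open and were not tested, and histone H3 lysine 79 methylation was not analysed here.

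A hypothesis tested was that EPZ5676 moves expression toward the ALDH1- profile. Over the 1993 genes called between populations with the replicate block, the population difference and the treatment effect had a correlation across genes of -0.27 (interval -0.36 to -0.19; Spearman -0.28), and of -0.12 over all genes tested. Of all 16327 genes tested, 3267 fell and 3579 rose with EPZ5676 averaged over both populations. Of 948 genes higher in ALDH1+, 239 fell and 148 rose with EPZ5676, and of 1045 lower in ALDH1+, 133 fell and 370 rose. These values go with such a movement, though a weak one. Genes are not independent replicates, and the interval over genes does not measure the spread between libraries. With the block 1384 genes differed between the populations in DMSO and 75 in EPZ5676. The interaction with the block called 0 genes, so these counts do not show a loss of population differences with EPZ5676. The correlation was not computed within each treatment. Nor was the level of the genes taken into account, although genes low in DMSO rose more often. ALDH1A1 fell with EPZ5676 but had a population difference of 0.18 (adjusted p = 0.37, 0.11 with the block), called in DMSO with the block (0.025) or without a filter (0.012) and in neither EPZ5676 nor the average. ALDH1A3 and the keratinocyte differentiation genes SPRR3, SPRR1B and KRT13, called higher in ALDH1+ with the block and rising with EPZ5676, go against it.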
